A study of Mus musculus with 2 samples.

How the data were processed

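Gene expression was measured in regulatory T (Treg) cells, the CD4 T cells that restrain other immune cells, of wild-type mice and of mice lacking miR-125a, a microRNA. Per the labels' protocols, CD4 T cells were first enriched with magnetic beads from the spleen and the cells positive for CD4 and high for CD25 were then sorted by flow cytometry. Equal amounts of RNA from several mice of a genotype were pooled, per the labels. The number of mice behind each pool is not given in the sources used here. Biotin-labelled cRNA was made from 6 ug of total RNA and hybridised to an Affymetrix Mouse Genome 430 2.0 array, a short-oligonucleotide array read in 1 colour. There was 1 array per genotype, so 2 arrays in all.

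The authors deposited log2 values, 1 for each of 45101 probe sets per array. MAS5, the Affymetrix summary method that subtracts the mismatch signal and scales each array by a trimmed mean, is the tool named in the submitters' processing notes, with no version. When the deposited log2 values were turned back to a linear scale, the mean after trimming 2% from each end was 500.0 on both arrays, which is the scale of every signal printed here. The lowest deposited value was 0 on the log2 scale, a linear signal of 1. It was held by 552 probe sets of the wild-type array and 473 of the miR-125a-deficient array, so these values are bounds. Detection calls were not used here. MAS5 values vary widely at low signal because mismatch signal is subtracted from each probe, which limits what a ratio between dim values can show.

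Of the probe sets, 34945 named 1 gene in the platform annotation, 932 named several, 64 were control probe sets and 9160 had no gene name in that table. Gene identifiers of 34741 of the probe sets naming 1 gene were found in a mouse RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols had to be changed. Probe sets naming several genes, controls and unnamed probe sets stayed out of the gene counts. Each of 18193 genes was represented by its probe set with the highest mean signal. The log2 ratio of a gene is log2 of the miR-125a-deficient signal plus 16.3 over the wild-type signal plus 16.3, the pseudocount being the 25th percentile of all signals of both arrays. Folds given with it are on that scale and understate the change of dim genes. Genes with a mean signal of at least 62.3, the median over probe sets, were kept, which left 10590 genes. No genome coordinates are printed. Chromosome and gene order, where used, are those of the RefSeq gene table.

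With 1 pooled sample per genotype there is no replicate and no test between genotypes, so no p-value is given, and genes were counted by size, at 2-fold or more. The only repeat measurement on these arrays is that of a gene by more than 1 probe set. The SD of the log2 ratio from this source was computed from 5037 genes with at least 2 probe sets past the minimum, as the SD of the difference between their 2 brightest probe sets divided by the square root of 2. It fell from 0.38 to 0.16 between the dimmest and the brightest of 10 equal groups of these genes. The value printed for a gene as "probe-set SD" is that of the group its mean signal falls in, not the gene's own spread. It covers isoform differences and the technical error that differs between probe sets. It leaves out error that a gene's probe sets share, and variation between mice. For each fixed gene list the median log2 ratio of the members past the minimum was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and a list was called apart at or below the 2.5th or at or above the 97.5th percentile. This describes the 2 arrays only. Members of a list are often regulated together, which random lists are not, so more lists fall outside this range than for unrelated genes.

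The gene lists, the minimum, the pseudocount and the rule for named genes were chosen before the data were examined. The 30 lists covered Treg identity, resting and activated T cell states, helper T cell programmes, signalling, metabolism, published targets of the miR-125 family and markers of other spleen cells. They were written from general knowledge. The named genes were the 10 highest and 10 lowest ratios among genes whose other probe sets past the minimum went the same way, leaving out unnamed clones and gene models, up to 2 highest and 2 lowest members of each list, and Spaca6, Foxp3, Il2ra, Ctla4, Cd4, Stat3, Ifng and Il13. Other genes named were chosen after their values were seen, apart from array controls, sex-linked genes and the basophil and mast cell markers. Alternatives were 3 other array scalings (equal medians, quantile normalization and loess with a span of 0.3), pseudocounts of 1 and of the median signal, no filter and a filter at the 75th percentile of mean signal, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, folds of 1.5 and 3, and random lists not matched on signal. A planned comparison of genes with and without a miR-125 seed site was not run, because no 3' UTR sequences were used here.

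The scripts were tested on simulated arrays with an SD of 0.2 on the log2 scale. Of 100 genes changed by 1.5 on the log2 scale, 93 were recovered at 2-fold, and of 100 changed by 2, 100 were. Among 10368 genes not changed, 7 reached 2-fold. The simulated SD was the same at every signal, whereas the probe-set SD of the real arrays rose towards low signals. These counts therefore test the scripts and are not error rates of the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.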

Results

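The data set holds the expression profiles of CD4+CD25hi Treg cells sorted from the spleens of mice 6 to 8 weeks old. One pool came from wild-type littermates and the other from miR-125a-deficient mice. The comparison asks which transcripts differ in Treg cells when miR-125a is missing. Each pool was read on 1 array, so every difference below compares 2 pooled RNA samples and has no replicate check. The median signal was 64.1 on the wild-type array and 62.4 on the miR-125a-deficient array. The log2 signals of the 2 arrays correlated with a Pearson r of 0.976 across the probe sets past the signal minimum, which are not independent replicates. The 18 probe sets of the spiked hybridisation controls had a median log2 ratio of 0.0027, with a range from -0.11 to 0.078, and the 24 probe sets of the poly(A) spike-in controls a median of -0.01, with a range from -0.33 to 0.31. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.22 for beta-actin on both arrays and 0.80 and 0.79 for Gapdh on the wild-type and miR-125a-deficient arrays. The ratios of Tfrc, 5.30 and 7.02, and of pyruvate carboxylase, 8.26 and 6.06, went opposite ways, and the 5' signals of Tfrc, 67.8 and 54.8, were too near the signal minimum for its ratio to be firm.

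The deletion itself could not be read from these arrays. None of the probe sets used here named the miR-125a, miR-99b or let-7e precursors, which lie together in the genome. Spaca6, the protein-coding gene beside this cluster, was below the signal minimum, at 5.62 in the wild-type and 35.5 in the miR-125a-deficient pool, so no ratio is given for it.

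Cytokines of type 2 helper T (Th2) cells were higher in the miR-125a-deficient pool, and Il9 and Il5 had the highest ratios of all genes past the signal minimum. The signal of Il9 was 7506 against 678 in the wild-type pool, that of Il5 860 against 88.6, that of Il13 2076 against 371 and that of Il4 1283 against 239. The corresponding log2 ratios were 3.44 for Il9, 3.06 for Il5, 2.44 for Il13 and 2.35 for Il4, with probe-set SDs of 0.19 for Il9, 0.28 for Il5, 0.20 for Il13 and 0.24 for Il4. Gata3, the transcription factor that directs Th2 differentiation, was 2.63-fold higher, at 2016 against 756, and Il24 was 2.45-fold higher. Csf2, which encodes the growth factor GM-CSF, was 4.36-fold higher. Gata3, Il24 and Csf2 were named after their values were seen.

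Of the 10 measured members of the Th2 list past the signal minimum, 6 were at least 2-fold higher, 0 were at least 2-fold lower and 4 lay between. The list's median log2 ratio was 1.34, above all 10000 random lists of its size and signal, whose central 95% ran from -0.19 to 0.21. The members that did not follow included Ccr4, a chemokine receptor of Th2 and Treg cells, with a log2 ratio of -0.04, and Maf, a transcription factor that activates Il4, with -0.82. Without Il4, Il5, Il9 and Il13, a choice made after seeing the data, the median of the 6 others was 0.26 and lay at percentile 97.54.

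**Figure D1:**
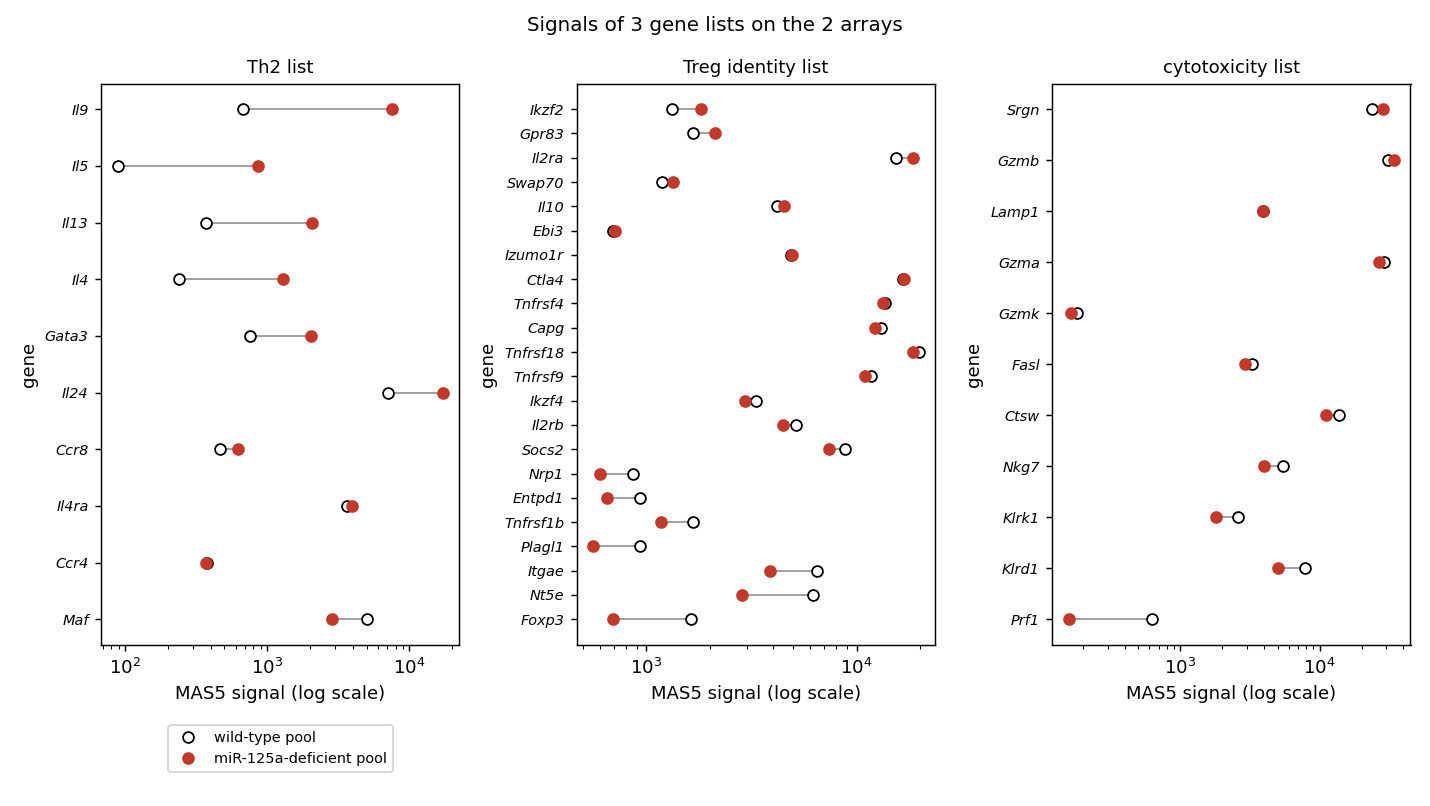
MAS5 signal (log scale) of each member past the minimum of the Th2, Treg identity and cytotoxicity lists, with 1 point per array: open for the wild-type pool, filled for the miR-125a-deficient pool. Il9, Il5, Il13 and Il4 lie to the right in the miR-125a-deficient pool, while Foxp3, Nt5e and Prf1 lie to the left.

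Genes of the other helper programmes past the signal minimum moved less. Measured members below it were not counted. Hlx of the Th1 list was at 4.63 in the miR-125a-deficient and 14.1 in the wild-type pool. Il1r1 of the Th17 list was at 87.3 against 5.40, and Ascl2 of the Tfh list at 93.2 against 18.2. In the Th1 list, 0 of 14 members reached 2-fold in either direction. Ifng, the main Th1 cytokine, had signals of 11536 in the wild-type and 14457 in the miR-125a-deficient pool, a 1.25-fold difference with a log2 ratio of 0.33 (probe-set SD 0.16). Tbx21, the Th1 transcription factor, had a log2 ratio of 0.24, while Cxcr3, a chemokine receptor of Th1 cells, had -0.94 and Ccl3 -0.75. The Th1 median of -0.19 lay at percentile 0.65 of random lists. Markers of CD8 T and NK cells, which share Ccl5 and Eomes with the Th1 list, had a median of -0.36 over 8 genes, 6 of them below 0, at percentile 0.42. With no filter on low signals it was -0.23 and lay within the random lists. In the Th17 list, 1 of 9 members, Batf, was at least 2-fold higher, Il17a was at 727 against 367 with a log2 ratio of 0.96, and Ccl20 and Ccr6 had log2 ratios of -0.80 and -0.78. The Th17 median of 0.21 lay at percentile 96.5, and in 3 of 10 alternative settings it was 0.42 and lay outside the random lists. In the follicular helper (Tfh) list, 0 of 10 members reached 2-fold, 6 were above 0, and its median of 0.30 lay at percentile 99.46, with a mean of 0.09. Il21 and Btla had the highest ratios of the Tfh list, at 0.73 and 0.56, and Bcl6, the Tfh transcription factor, the lowest, at -0.78. Bcl6 was near the signal minimum, at 48.9 against 95.9, and its other probe set, below the minimum, had a ratio of 0.36. The other probe set of Il21 had a log2 ratio of 2.02, at 1610 against 384, and with the mean over probe sets Il21 passed 2-fold, at 1.38.

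Across 24 effector cytokines and chemokines past the minimum, 5 were at least 2-fold higher and 0 at least 2-fold lower. The 5 were Il4, Il5, Il9, Il13 and Csf2. The median of the whole list was 0.07, at percentile 79.1. Xcl1, a chemokine of activated T cells, had a log2 ratio of -0.75.

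Foxp3, the transcription factor that defines Treg cells, was 2.32-fold lower in the miR-125a-deficient pool, at 694 against 1631, with a log2 ratio of -1.21 (probe-set SD 0.20) from the 1 probe set that measured it. Nt5e, which encodes CD73, an enzyme that makes adenosine at the cell surface, was 2.18-fold lower, at 2842 against 6222. These were the members of the Treg identity list that differed by at least 2-fold. The other 20 of its 22 measured members lay between, among them Ctla4, an inhibitory receptor, with a log2 ratio of 0.02, and Il2ra, which encodes CD25, with 0.27. Ikzf2 and Gpr83, both typical of Treg cells, had ratios of 0.45 and 0.34, the latter with its other probe set at -0.07. Itgae, Plagl1, Tnfrsf1b, Entpd1 and Nrp1, named after their values were seen, had ratios of -0.73, -0.73, -0.51, -0.51 and -0.51. The median of the list was -0.09, at percentile 2.24, and it lay within the random lists in 3 of 10 alternative settings, with percentiles up to 10.7. Cd4 had a log2 ratio of -0.15, and the T cell lineage list had 0 of 12 members at 2-fold and a median of -0.06, at percentile 8.89.

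Genes of T cell activation and quiescence went both ways. Of 26 genes of activated or effector Treg cells, 2 were at least 2-fold higher and 0 lower. Batf, a transcription factor of effector T cells, stood at 4598 against 1790, 2.55-fold higher, and Cd83, an activation marker, at 3528 against 1084, 3.22-fold higher. The median of the list was nonetheless below 0, at -0.13 and percentile 0.22, with Cxcr3 at -0.94 and Lgals3 at -0.86. Of 14 genes of resting T cells, Klf2, which maintains quiescence and recirculation, was 2.59-fold lower and Txk, a kinase of the Tec family, 3.25-fold lower. Satb1 and Dapl1 of the same list had ratios of 0.84 and 0.83, and the list's median was -0.13, at percentile 1.57. It was -0.03, at percentile 22.7, without probe sets that can match several transcripts, and lay within random lists not matched on signal, at percentile 8.94. Of 21 immediate early genes, Klf4 and Btg2, both of which restrain proliferation, were 2.18-fold and 2.16-fold lower, 0 were at least 2-fold higher, and the median was -0.12, at percentile 1.5. The other probe sets of Klf4 and Btg2 had ratios of -0.27 and -0.79, and with the mean over probe sets both genes lay under 2-fold, at -0.70 and -0.95.

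In the cytotoxicity list, Prf1, which encodes perforin, was the 1 of 11 members that reached 2-fold. It was 3.67-fold lower in the miR-125a-deficient pool, at 158 against 623. Among the 10 lowest ratios of genes whose probe sets agreed in direction were Gzmg, Gzme and Gzmd, granzymes of 1 gene cluster, at 4.61-fold, 4.20-fold and 4.17-fold lower. The other members of the list lay between Klrd1, at -0.64, and Srgn, at 0.26, with Klrk1 at -0.53, Nkg7 at -0.45 and Ctsw at -0.30, the last 3 named after their values were seen. Gzmb had signals of 30999 in the wild-type and 34356 in the miR-125a-deficient pool. The list's median was -0.17, at percentile 0.87. Gzmd, Gzme and Gzmg are close sequence relatives, so their probe sets can share transcripts. Markers of CD8 T and NK cells, whose list shares Klrd1 and Gzma with this one, were measured beside it. Cd8a and Cd8b1, the chains of CD8, had log2 ratios of -0.54, at 295 against 435, and -0.38, at 332 against 438, and were named after their values were seen. Ccl5 had -0.59, whereas the NK cell receptors Klra7 and Klre1 had 0.92 and 0.58.

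Genome-wide, 114 genes were at least 2-fold higher and 127 at least 2-fold lower in the miR-125a-deficient pool, together 2.28% of the 10590 genes past the minimum. At 4-fold, 13 were higher and 10 lower. After loess scaling the split was 145 higher and 100 lower, so the share of higher genes moved from 47.3% to 59.2%. Beside the cytokines, the highest ratios of genes whose probe sets agreed were those of Oaf, Akr1c18, Pde1a, Tuba8, Scin and Insl5. Akr1c18, an enzyme that inactivates progesterone, was 6.12-fold higher, at 4361 against 699. Scin, an actin-severing protein, was 4.68-fold higher and Insl5, a peptide hormone, 4.47-fold higher. Oaf and Tuba8 had signals of 9.71 and 16.6 in the wild-type pool, near or below the pseudocount. The lowest such ratios were those of Zfp358, Cdhr3, Stxbp6, Epcam, Gzmg, Isg20, Gzme, Gzmd, Serpinb1a and Prf1. Stxbp6, which regulates vesicle fusion, was 6.90-fold lower, Epcam, an adhesion molecule, 5.95-fold lower, Isg20, an exonuclease induced by interferon, 4.25-fold lower, and Serpinb1a, an inhibitor of neutrophil proteases, 4.02-fold lower. The other probe set of Epcam had a log2 ratio of -0.86, and the mean over its probe sets was -1.71 in place of -2.57. That of Stxbp6 had -1.92, and the mean over its probe sets was -2.35 in place of -2.79. The probe set used for Stxbp6 had a signal of only 59.0 in the miR-125a-deficient pool. Zfp358 and Cdhr3 had signals of only 7.21 and 7.59 in the miR-125a-deficient pool.

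**Figure D2:**
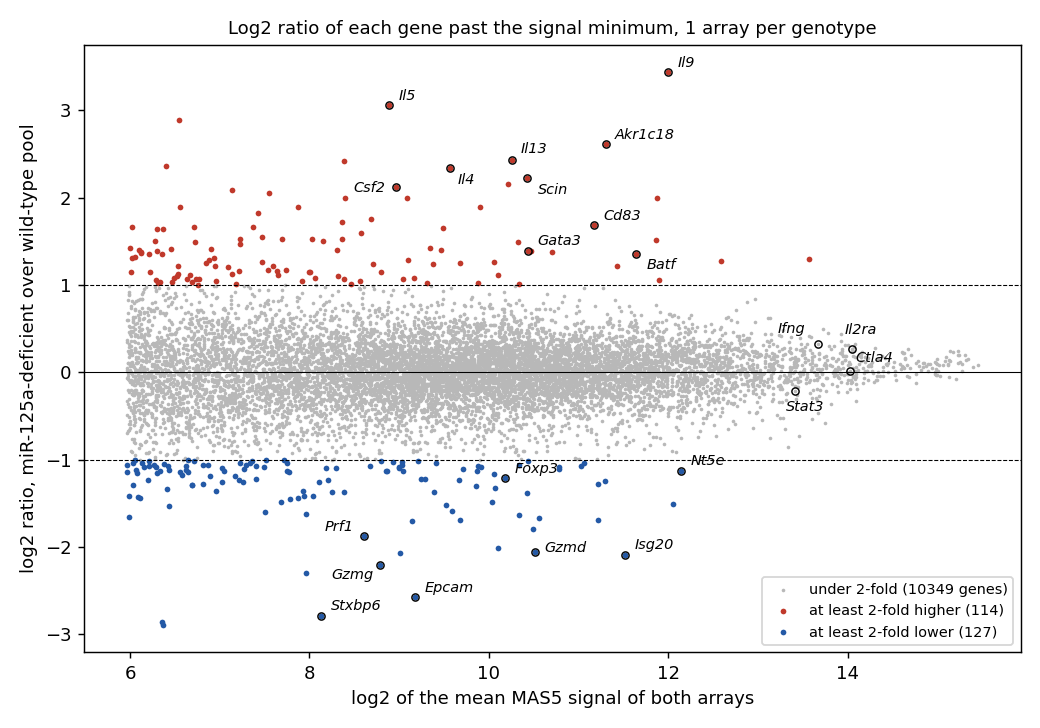
Log2 ratio of the miR-125a-deficient over the wild-type pool (vertical) against log2 of the mean MAS5 signal of both arrays (horizontal) for each of 10590 genes, with 2-fold marked by dashed lines and selected genes by rings. Il9, at 3.44, has the highest ratio, and the spread of ratios narrows towards high signals.

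Stat3, a transcription factor that relays IL-6 signals, has been described as a miR-125a target in Treg cells, as have Ifng and Il13. The Stat3 log2 ratio was -0.21 (probe-set SD 0.16), at 10115 in the miR-125a-deficient against 11703 in the wild-type pool, and its 4 probe sets ranged from -0.26 to 0.44. Of 25 published miR-125 targets past the minimum, 2 were at least 2-fold higher, Il13 and Il1rn, an antagonist of IL-1, the latter at 2058 against 777, and 0 were at least 2-fold lower. Bmf, a promoter of apoptosis, had a log2 ratio of -0.77 and Mcl1, a survival factor, -0.72, with the 5 other probe sets of Mcl1 between -0.29 and -0.12. The list's median was -0.05 and its mean 0.08, so the 2 differ in sign, and the median lay at percentile 9.14 of random lists. Since Stat3, Ifng and Il13 may have been chosen on these samples, they are not independent evidence of its direction. Without them, a choice made after seeing the data, the median was -0.08 at percentile 6.28. In cytokine receptor and JAK-STAT signalling, 0 of 28 genes reached 2-fold. The median was -0.13, at percentile 0.19, with Ifngr1, a chain of the interferon gamma receptor, lowest at -0.79 and Stat5a highest at 0.47, although the probe sets of Stat5a disagreed, with the other at -0.06.

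Proliferation genes were shifted by little but nearly all in 1 direction. Of 28 cell cycle genes, 27 had a ratio above 0 and 0 reached 2-fold, and the median of 0.22 lay at percentile 99.97. Rrm2, a subunit of ribonucleotide reductase, had a ratio of 0.62, at 5841 against 3784, and Kif11, a mitotic motor, -0.26. The sign of Kif11 turned with the probe set, since its others had ratios of 0.30 and 0.46 and the mean over probe sets was 0.17. Of 22 genes of oxidative phosphorylation, 19 were above 0 with a median of 0.16, at percentile 99.2, led by Ndufa4 and Atp5g1, both at 0.55. Glycolysis, cholesterol synthesis and ribosomal protein genes had medians of 0.05, -0.04 and 0.10 and lay within the random lists. Rps27 was the 1 ribosomal protein gene at least 2-fold lower, at -1.01, and lay under 2-fold with each of the 3 other scalings and a pseudocount at the median signal, at -0.93 in the setting nearest to 0. Of 14 heat shock and stress genes, Gadd45a was 2.02-fold higher, and the median of 0.15 lay at percentile 95.8. The median lay outside the random lists with the mean over probe sets, at 0.24, and without probe sets that can match several transcripts, at 0.32. With a pseudocount at the median signal, Gadd45a lay under 2-fold, at 0.89. Among 18 interferon-stimulated genes, Usp18, a brake on interferon signalling, was 3.73-fold higher and Oas1a 2.11-fold higher, whereas Gbp3 and Gbp2 had ratios of -0.66 and -0.64. Oas1a lay under 2-fold with that pseudocount, at 0.77. Their median was -0.06 and their mean 0.12, with the median at percentile 19.8. With the filter at the 75th percentile of mean signal their median was -0.20 and lay outside the random lists.

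Markers of other spleen cells were measured beside these groups. Of 21 measured macrophage, monocyte and dendritic cell markers, 8 were past the minimum, 5 of them below 0, with a median of -0.44 at percentile 0.25 (-0.20 and within the random lists with no filter), and Fcer1g, a signalling chain of Fc receptors, was 2.03-fold lower, at 103 against 226. Fcer1g lay under 2-fold with each of the 3 other scalings and a pseudocount at the median signal, at -0.80 in the setting nearest to 0. Of 8 B cell markers past the minimum, 0 reached 2-fold, with a median of -0.02 at percentile 47.1, and Ighm, the heavy chain of IgM, had the lowest ratio, -0.95, although its 4 probe sets past the minimum ranged from -0.95 to 0.41. Igha, the heavy chain of IgA, was lower, at 376 against 1160 with a log2 ratio of -1.58, while Mzb1, another plasma cell gene, had a log2 ratio of -0.02. The plasma cell list had 3 members past the minimum and a median of -0.16, at percentile 16.5, which with no filter was -0.46 and outside the random lists. The 6 platelet genes went both ways, with Gp9 and Gp1bb at 0.61 and 0.54 and Itga2b and Treml1 at -0.43 and -0.57. Their median was 0.44, at percentile 99.2, and their mean 0.17. None of the 13 measured neutrophil markers passed the minimum, and 2 erythroid markers and 1 endothelial marker did, with ratios under 2-fold. In all, 14 of 25 lists lay outside the random lists, 5 above and 9 below, and 1 of them, the Th2 list, had a median beyond 0.5 in size. The Th2, Tfh and cell cycle lists stayed outside in all 10 alternative settings. The other lists called apart lay within the random lists in 1 or 2 of the settings they could be computed in, and the cytotoxicity list, like the Treg identity list, in 3.

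**Figure D3:**
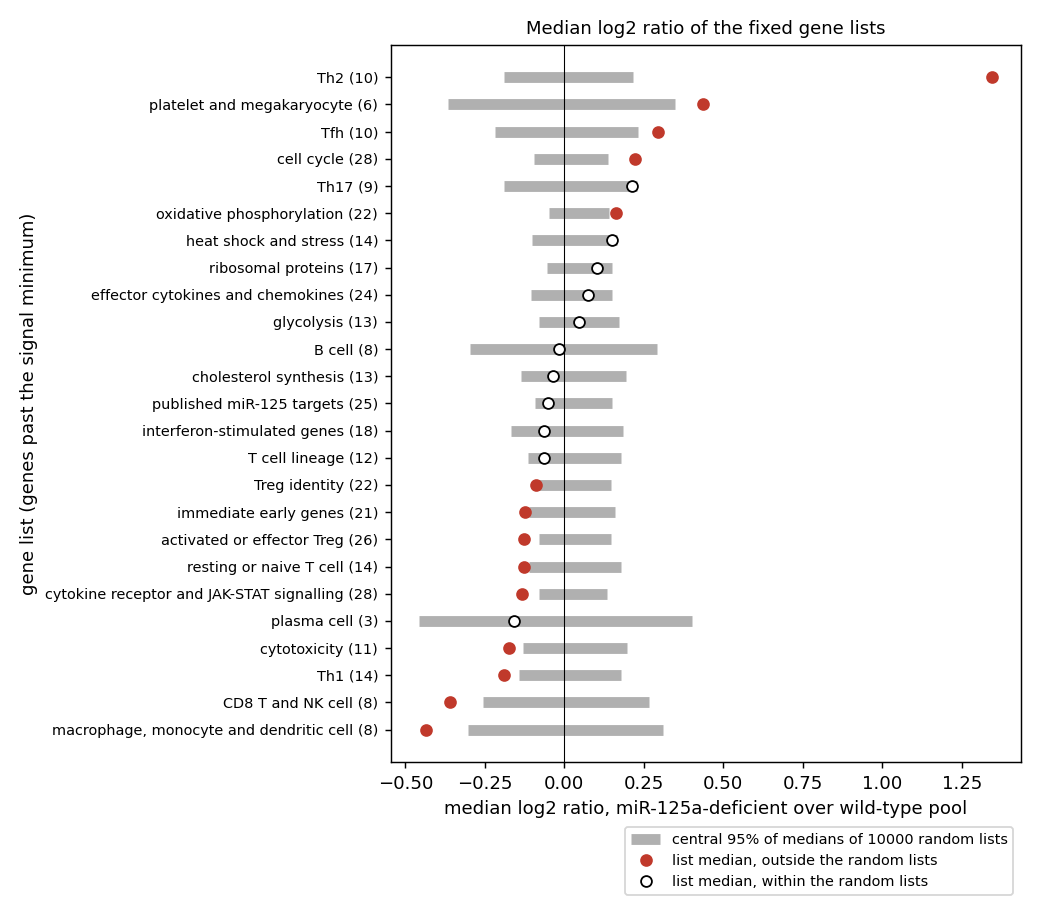
Median log2 ratio of each of 25 gene lists (points; filled where outside the random lists) and the central 95% of medians of 10000 random lists of the same size and signal (bars), with the number of genes in parentheses. The Th2 list, at 1.34, stands apart from all others, and the 13 other lists outside the bars lie between -0.44 and 0.44.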

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

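Signals outside the gene counts also differed between the pools. Of the 10590 genes that were counted, 114 were at least 2-fold higher and 127 at least 2-fold lower in the miR-125a-deficient pool. Of 2703 probe sets past the signal minimum with no gene name, 17 were at least 2-fold higher in the miR-125a-deficient than in the wild-type pool and 66 at least 2-fold lower. Of 568 that name several genes, 17 were at least 2-fold higher and 12 lower. They were singled out because no comparison of named genes used them, and with 1 array per genotype no spread stands behind them. Of the tests below, those on the genes restricted to Treg cells and on the Treg identity list were chosen after the result was seen.

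The first pattern weighed is the number of genes at 2-fold, 241. Measurement noise was drawn 1000 times from the differences between probe sets of the same gene at the same signal, which gave a median of 56 genes at 2-fold and at most 81. Under the 3 other array scalings the count was 245 to 251. The draws argue against noise that differs between probe sets as the whole cause, and the counts under other scalings against the array scaling. Error that a gene's probe sets share is not in the draws, so noise of that kind stays open. The dimmest group drawn from ran up to a signal of 197, so noise of the dimmest genes may be understated. Differences between the mice that went into each pool, which are not tied to miR-125a, cannot be told apart from the genotype, because each genotype is 1 pool.

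The second pattern is the higher signal of Il4, Il5, Il9 and Il13. Under the 3 other scalings the lowest log2 ratio of the 4 genes was 2.39, which argues against the array scaling. Basophils and mast cells also make these cytokines, but the 4 of their markers past the minimum (Cpa3, Fcer1a, Gata2 and Kit) had a median log2 ratio of -0.26 (SD among random lists 0.23), Mcpt8 was below the minimum on both arrays, and the CD4 sort would remove such cells, so the values argue against them. Conventional Th2 cells with high CD25 inside the sort gate stay open: the 5 genes largely restricted to Treg cells, Foxp3 left out, had a median log2 ratio of 0.028 (SD 0.14), and a small share of such cells could raise the cytokines without moving these genes. An effect of the missing microRNA on the Treg cells themselves is the biological explanation the design names, and it remains untested beside these.

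The third pattern is the lower Foxp3 signal. Its log2 ratio was at most -1.16 under the 3 other scalings, which argues against the array scaling. If fewer cells of the pool were Treg cells, other Treg genes would fall with Foxp3. The median of Ikzf2, Ikzf4, Nrp1, Gpr83 and Izumo1r lay 1.24 above the Foxp3 ratio (SD 0.14 among random lists). That of all 21 other members of the Treg identity list lay 1.13 above it (SD 0.060 among random lists). These SDs describe medians of random lists, so neither gap can be counted in them. They leave out the spread between Treg genes, from -0.51 for Nrp1 to 0.45 for Ikzf2 in the smaller set. They also leave out the Foxp3 probe-set SD of 0.20. Il2ra, among the 21, was held by the sort on its product and cannot report the share. Foxp3 had the lowest ratio of the list, so any set of its other members would lie above it. The smaller set was also chosen after the result was seen and leaves out Nt5e, the next lowest. Its genes did not fall as far as Foxp3, but they cannot decide whether the share of Treg cells was lower. Of the 21, 6 lay at -0.5 or below: Nt5e at -1.13, Itgae and Plagl1 at -0.73, and Tnfrsf1b, Entpd1 and Nrp1 at -0.51. Activated conventional T cells can express many of the others, so a lower share of Treg cells stays open. Lower Foxp3 transcription per cell is a hypothesis these arrays leave open as well, and it rests on 1 probe set.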

How the results depend on the processing

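No paired analysis was possible because each genotype has 1 array and no replicate numbers. For the same reason no sample could be left out. The 2-fold counts of 114 higher and 127 lower genes changed to 58 and 57 with a pseudocount at the median signal, to 809 and 580 with no filter on low signals, to 35 and 47 with a filter at the 75th percentile of mean signal, to 530 and 613 at 1.5-fold, and to 30 and 20 at 3-fold. Fewer or more genes enter under the filters by construction, and a larger pseudocount shrinks the ratios of dim genes. All 114 higher genes were kept under the 3 other scalings, as were 108 of the 127 lower genes with equal medians, 110 with quantile normalization and 99 with loess. Il4, Il5, Il9 and Il13 stayed at least 2-fold higher and Foxp3 at least 2-fold lower under every alternative that gave them a value. Each of these genes was measured by 1 probe set, so only the other scalings and pseudocounts could move their ratios. The Th2 list stayed above the random lists in all 10 planned settings, with medians from 1.29 to 2.35. The Treg identity list came to lie within the random lists with no filter (median -0.089), without probe sets that can match several transcripts (-0.094) and against unmatched random lists (-0.089), the activated Treg list against unmatched random lists (-0.13), and the Th1 list with the mean over probe sets (-0.15). The Th17 list, within the random lists in the report, had a median of 0.42 and lay outside them with no filter, with the higher filter and without probe sets that can match several transcripts, and was 0.084 with the mean over probe sets. Of the other lists, those that came to lie within the random lists did so without probe sets that can match several transcripts (resting T cell -0.034, cytotoxicity -0.17, immediate early genes -0.091), with the mean over probe sets (cytotoxicity -0.14, cytokine receptor signalling -0.10, oxidative phosphorylation 0.11, CD8 T and NK cell -0.26), with no filter (CD8 T and NK cell -0.23, macrophage -0.20), with the higher filter (platelet 0.37) and against unmatched random lists (resting T cell, cytotoxicity and immediate early genes). Those that came to lie outside were the heat shock list with the mean over probe sets (0.24) and without the probe sets named (0.32), the interferon list with the higher filter (-0.20) and the plasma cell list with no filter (-0.46). The cause was not tested. Of 35 named genes at 2-fold, 29 stayed there under every alternative that gave them a value, whereas Klf4 and Btg2 lay under it with the mean over probe sets, Gadd45a and Oas1a with a pseudocount at the median signal, and Fcer1g and Rps27 with that pseudocount and each of the 3 other scalings. Il17a, Il21, Klra7 and Tyms, under 2-fold in the report, passed it under at least 1 alternative. The sign turned under at least 1 alternative for Kif11, Cd247, Ccr4, Ctla4, Mzb1, Rps6, Uqcrc2 and Xist, none of which was at 2-fold. None of the list medians called apart and none of the named genes at 2-fold changed direction. Over all lists and planned and added settings, 224 of 249 values stayed on the same side, 18 came to lie within the random lists and 7 came to lie outside. Of the 249, 24 moved by more than the random lists' SD. Of the named genes' ratios 956 moved by less than the probe-set SD and 34 by more. The seed-site comparison and its alternatives were not run. Genes near the signal minimum are the least certain: Zfp358 ran from -4.27 to -1.65, Cdhr3 from -4.20 to -1.64 and Oaf from 1.73 to 4.06, while Il9 ran from 3.35 to 3.49.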

Other observations

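Several further genes differed by at least 2-fold; the genes of this paragraph were named after their values were seen. Batf3, a partner of the AP-1 factors related to Batf, was 2.87-fold higher in the miR-125a-deficient pool, at 5537 against 1920, and Dennd5a, a regulator of membrane traffic, was 3.99-fold higher. Dntt, which adds bases at receptor gene joints in early lymphocytes, was 3.22-fold lower, with its 3 probe sets past the minimum between -1.92 and -1.22, Ramp1, part of the CGRP receptor, was 3.24-fold lower, and Igf1 was 3.02-fold lower. Within the granzyme family, Gzmf was 2.57-fold lower and went with Gzmd, Gzme and Gzmg, whereas Gzmc, Gzma and Gzmk had log2 ratios of -0.35, -0.12 and -0.13.

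The labels describe cells taken through a sort and name no culture or stimulation. The arrays showed signals of 11536 and 14457 for Ifng, 30999 and 34356 for Gzmb and 4495 and 5027 for Mki67, named after its values were seen, in the wild-type and miR-125a-deficient pools. The highest signals of any probe set were 45038 and 47226. Probe sets differ in brightness per transcript, so these are not relative abundances. The sources used here do not say whether the cells were stimulated before RNA extraction. A difference of that kind between the pools could not be told apart from the genotype.

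Xist was at 18564 in the wild-type and 18810 in the miR-125a-deficient pool, and the Y-linked genes Eif2s3y, Kdm5d and Uty were below the signal minimum on both arrays.

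A hypothesis formed after the list values were seen was that targets of miR-125 rise as a class when miR-125a is missing. The median of the 25 published targets lay at percentile 9.14 of random lists, within their central 95%, so no shared rise was seen, but members went both ways and a small shared shift or an effect on translation alone could be missed. The related miR-125b has the same seed and may act on the same transcripts.

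A further hypothesis, tested without prior sight of the values, was that DNA from another strain around the deleted locus on chromosome 17 would bring a local excess of differing genes. On chromosome 17, 6 of 545 genes, 1.10% (95% Wilson interval 0.51% to 2.38%), differed by at least 2-fold, against 2.33% of 10031 genes on the other chromosomes, which argues against such an excess over the chromosome as a whole. Of the 20 measured genes nearest to the locus 0 reached 2-fold. With 2.28% of all genes at 2-fold, so small a set could not show or exclude a local excess. Log2 ratios of the 20 ran from -0.62 to 0.83, with a median of -0.06. Among them Zfp160, Zfp54, Zfp51, Zfp53, Zfp52 and Zfp948 were all lower, between -0.62 and -0.33, whereas Zfp677 had 0.31 and Prdm9 0.83. Smaller local differences from flanking DNA therefore stay open.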
